A study of Drosophila melanogaster with 2 samples.

How the data were processed

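The 2 libraries analysed formed 1 group, biological replicates 1 and 2 of an RNA immunoprecipitation followed by sequencing (RIP-seq) directed at qkr58E-1 in Drosophila S2R+ cells. Per the labels, the cells carried qkr58E-1 under the copper-inducible MtnA promoter, with HA-tagged and FLAG-tagged forms both listed for each library, and copper sulfate was added at 0.35 mM over 24 hours. A control experiment that the labels point to was not analysed here, so the values below are levels in the immunoprecipitated RNA and not enrichments over a control.

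Each library came as a per-base signal track on the dm3 assembly. Per the file headers beside the tracks, the authors made the deposited signal from the alignment of each replicate separately, over all reads, and normalized it; the aligner, its limits on intron length and the treatment of reads with several matches are not given in the sources used here. The scale was worked out from the values. Each signal value was a whole multiple of the smallest value of its library (0.0931 in replicate 1 and 0.0898 in replicate 2), with a largest deviation of 5.82e-10 from a whole number. Signal times length summed to 50000000 in both libraries. Of the isolated stretches on the arms that were 1 read deep, 95.3% of 78791 in replicate 1 and 95.6% of 82540 in replicate 2 were 50 nt long, so reads were taken as 50 nt and the sum as 1000000 reads. The deposited signal is therefore coverage scaled to 1000000 reads, and dividing by the smallest value gave whole reads over each base. The totals were 10735444 reads in replicate 1 and 11129711 reads in replicate 2. The tracks hold no strand. Because the scaling fixes the total, a larger share on a few sequences lowers the values of the rest.

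Signal was summed per chromosome and averaged in 1 kb bins, counted from the first base of each sequence. A read equivalent is the summed coverage divided by 50. Shares of reads are given with 95% Wilson binomial intervals in each library; reads can be copies of one molecule, so these intervals cover counting error only. Replicates were compared on log2(signal + 0.0898), the pseudocount being the smaller of the 2 unit steps. These are steps in coverage at a base, not in the mean of a bin. A bin was called different between replicates when its log2 ratio, centred on the median of the 10% of bins with the highest mean signal, was at least 1 in size. Values are the mean ± SD of the 2 replicates (n = 2). With 1 group and no control there was no test between groups, and correlations across bins, introns or units carry no p-value, because these are not independent replicates.

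Splicing was read from the tracks themselves. A candidate intron was a gap of 40 nt to 20 kb between a drop in coverage and the next rise, each of at least 10 reads and at least 20% of the coverage beside it, with both steps within 1.5 times of each other. Only gaps called at the same first and last base in both replicates were kept. The signal inside was the mean coverage of the gap divided by the mean coverage of the 50 nt on each side, and a candidate intron with 20% or more in both replicates is called retained, a word that stands only for that ratio. Stretches with at least 3 reads per base in both replicates that shared introns joined were called spliced units; neighbouring genes that touch may be merged in one. These definitions, and the introns and units named in the text, were chosen after their values were seen. The bin and chromosome results, the alternatives tried on them, apart from 1 on the arms alone that was added later, and the rule for named bins were fixed before the data were examined: the 10 bins with the highest mean signal, the highest bin of each chromosome, and the 3 bins of the top 10% with the largest centred ratio in each direction.

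The procedures were tested on simulated data that were simpler than the real tracks. Bins varied by counting error alone, and introns lay in separate transcripts with evenly spread read starts. The simulation held no stacks, repeats or overlapping genes, so the rates below need not hold for the real tracks. Of 7364 simulated bins, 63 of 63 changed 3-fold, 69 of 69 changed 4-fold and 0 of 68 changed 1.5-fold passed the 2-fold rule, as did 0 of 7164 unchanged bins. Of 1777 simulated introns, 94.3% were found, and 1676 of 1677 calls were true. Simulated introns with 10%, 30% and 50% of unspliced RNA gave median ratios of 10.5%, 29.6% and 49.8%.

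Gene-level results were planned with 23 gene lists fixed before the data were examined, but the gene table at hand belongs to Release 6, another assembly, and coordinates were not carried between assemblies. No gene is therefore named at any position, and gene lists, the qkr58E-1 transcript, annotated introns, transcript ends and sequence motifs were not analysed here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.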

Results

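RNA that precipitated with qkr58E-1, a KH-domain protein of the STAR family of RNA-binding and splicing regulators, was sampled by immunoprecipitation from S2R+ cells, a line derived from Drosophila embryos with features of blood cells. The tracks of the 2 biological replicates held 10735444 read equivalents in replicate 1 and 11129711 in replicate 2. The number of reads sequenced cannot be read from the tracks. Coverage reached 27.2 Mb of the dm3 assembly in replicate 1 and 27.3 Mb in replicate 2. Nothing in the labels orders the replicates, and the labels do not give which tagged form was precipitated in which library, so a difference of tag between them cannot be told from the spread of the experiment.

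Most of the signal came from the euchromatic arms, and about 1 read in 5 fell on unplaced or heterochromatic sequence, mostly in a few tall stacks. The arms 2L, 2R, 3L, 3R, X and 4 together held 77.3% ± 3.11 of the signal (SD, n = 2). Unplaced sequence (U), which in this assembly gathers scaffolds that could not be assigned to a chromosome, held 16.9% ± 2.06. The heterochromatic scaffolds held 3.95% ± 1.57 and the mitochondrial sequence 1.81% ± 0.530. The XHet scaffold alone held 1.92% in replicate 1 and 4.22% in replicate 2, a log2 difference of 1.14. With each base capped at the 99th percentile of covered bases, the share of U was 0.696%, that of XHet 0.0690% and that of the mitochondrial sequence 0.243%. Among the arms, 3R held 17.5% ± 0.575, 3L held 17.4% ± 1.15, 2R held 16.6% ± 0.378, X held 13.3% ± 0.505 and 2L held 11.6% ± 0.424. The small chromosome 4 held 0.789% ± 0.0737. Counting error was small against these differences: the share of 4 had a Wilson 95% interval of 0.836% to 0.847% in replicate 1 and of 0.732% to 0.742% in replicate 2. The Y scaffold was nearly empty, with 58 read equivalents in replicate 1 and 80 in replicate 2.

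Signal of 1 or more was found in 6.10% of the 1 kb bins of X, in 5.22% of those of 2L, 7.42% of 2R, 5.94% of 3L, 6.25% of 3R and 8.48% of chromosome 4. Among these bins, which the same limit selects and so brings close together, the median was 1.92 ± 0.0987 on X, 1.96 ± 0.0334 on 2L, 1.82 ± 0.116 on 2R, 1.96 ± 0.0816 on 3L and 1.99 ± 0.102 on 3R (coverage scaled to 1000000 reads, SD, n = 2). On chromosome 4 it was 1.58 ± 0.158. Long stretches without a single read in either library lay between the transcribed regions. There were 123 such stretches of 20 kb or more on 3R, 110 on 2L, 102 on 3L, 96 on X, 58 on 2R and 0 on 4. The longest, on 3L from 13685272 to 13830010, spanned 145 kb. Assembly gaps and repeats to which reads could not be assigned would also appear as silent.

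A small number of bins held much of the signal. Of 73631 bins with signal, the 736 highest (1%) held 49.8% of the signal in replicate 1 and 52.6% in replicate 2, a mean of 51.2% ± 2.04. The highest bin, U from 5727001 to 5728000, had a mean coverage of 4222 ± 446 on that scale and by itself held 8.44% of the signal. It was followed by 3L from 2113001 to 2114000, with 1132 ± 144 and 2.26% of the signal. The next 6 bins lay on unplaced and heterochromatic sequence. XHet from 191001 to 192000 had 709.8 ± 557, from 316 in replicate 1 and 1104 in replicate 2 (centred log2 ratio 1.90), so its place among the 10 depends on the library. U from 9063001 to 9064000 had 709.4 ± 112. U from 6962001 to 6963000 had 699 ± 10.4, U from 9660001 to 9661000 had 667 ± 59.8, and U from 4571001 to 4572000 had 603 ± 131. XHet from 184001 to 185000 had 513 ± 164. In these 6 bins the coverage was concentrated in spikes whose width at 50% of the summit height was 50 to 54 nt in both replicates. The adjacent bins 2R from 10246001 to 10247000, with 463 ± 6.21, and 2R from 10245001 to 10246000, with 354 ± 16.6, completed the 10 highest. Their summits were broader, 111 to 217 nt at 50% of the height.

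The rule also named the highest bin of each of the other sequences, which need not stand far above the next. The highest bin was 3R from 5609001 to 5610000 at 163 ± 29.1, 2L from 2756001 to 2757000 at 122 ± 25.5, X from 11473001 to 11474000 at 84.8 ± 43.9 and chromosome 4 from 341001 to 342000 at 19.3 ± 2.03. On the heterochromatic scaffolds it was 2RHet from 2362001 to 2363000 at 26.6 ± 2.59, 3RHet from 790001 to 791000 at 25.2 ± 0.216, 3LHet from 2387001 to 2388000 at 10.4 ± 0.982 and 2LHet from 168001 to 169000 at 8.76 ± 0.334. On YHet, the bin from 328001 to 329000 reached 0.137 ± 0.0353, from 24 and 36 read equivalents. On the mitochondrial sequence it was the bin from 12001 to 13000, at 279 ± 63.5.

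Signal levels were closely related between the 2 replicates over the whole set of bins, though some of the highest bins differed. Across the 73631 bins, Pearson's r of the log2 signal was 0.991 and Spearman's rho was 0.914. The mitochondrial bin from 17001 to 18000 held 1 read in replicate 2, a signal of 0.00449, far below the pseudocount. The pseudocount therefore draws the log2 values of low bins together, and Pearson's r says little about them. A smaller pseudocount was not tried. Among the 7364 bins of the top 10%, which held at least 94 read equivalents in each library, the centred log2 ratio of replicate 2 over replicate 1 had an SD of 0.28, against a median of 0.10 for counting error alone. The ratio reached 2-fold in 49 bins (0.665%), among them the leading bins of XHet and of X (53.8 and 115.9), and 34 were higher in replicate 2 and 15 in replicate 1. These bins were unevenly placed: 29 of the 7212 arm bins, 14 of the 138 unplaced or heterochromatic bins and 6 of the 14 mitochondrial bins. The bins with the largest ratios toward replicate 1 were U from 5297001 to 5298000 (centred log2 ratio −2.64), the mitochondrial bin from 8001 to 9000 (−2.29) and that from 14001 to 15000 (−2.27). Toward replicate 2 they were 3L from 1668001 to 1669000 (2.09), U from 9882001 to 9883000 (2.01) and 2R from 13504001 to 13505000 (2.01). Summits in both U bins, the 2R bin and the mitochondrial bin from 8001 were 50 or 51 nt wide at 50% of their height. Those in the 3L bin were 24 and 28 nt wide, and those in the mitochondrial bin from 14001 were 125 and 136 nt wide. Much of the signal in such bins can come from a narrow stack, so their reads need not be independent.

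**Figure D1:**
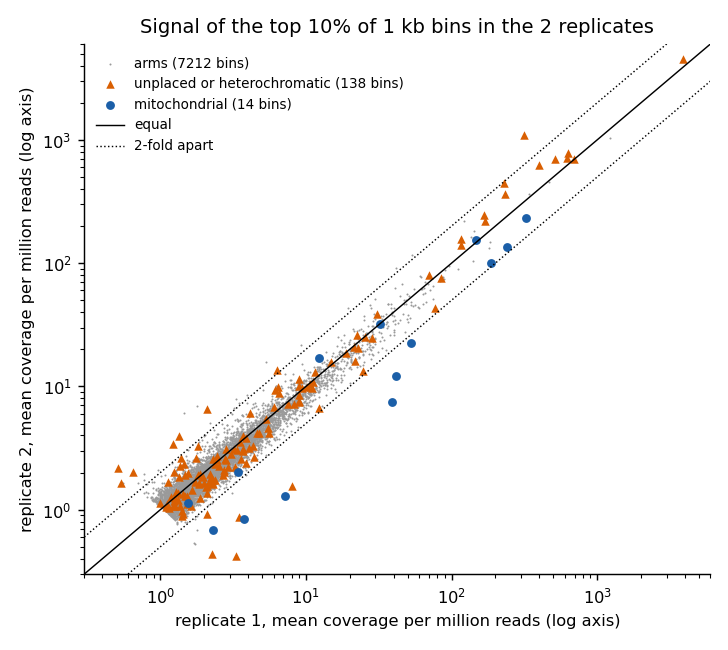
Mean coverage scaled to 1000000 reads of the 7364 highest 1 kb bins in replicate 1 (x axis, log) and replicate 2 (y axis, log); each point is a bin, the solid line marks equal signal and dotted lines a 2-fold difference before centring. Arm bins lie close to the diagonal, and several of the 14 mitochondrial bins lie below it.

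Splice junctions were visible in the immunoprecipitated RNA as paired steps in coverage. Replicate 1 gave 11808 candidate introns and replicate 2 gave 11168, and 8606 of them had the same first and last base in both, 72.9% of those in replicate 1 and 77.1% of those in replicate 2. Their most frequent length was 62 nt, found 371 times, and 3834 of them (44.6%) measured 55 to 70 nt, the short intron class that is typical of Drosophila genes. The median was 72 nt, and 111 were longer than 10 kb. The mitochondrial sequence, whose genes have no introns, gave 0 candidate introns, and unplaced sequence gave 15. Candidate introns were densest on chromosome 4, at 508 per covered Mb, against 277 on X and 383 on 2R, the lowest and highest of the large arms.

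Of the 5 candidate introns with the most junction reads by the mean of both libraries, 3 were short (74, 85 and 263 nt) and 2 were longer than 2 kb. The highest by that mean was 2L from 2756171 to 2756244, 74 nt long and crossed by 4033 reads in replicate 1 and 2985 in replicate 2. In replicate 2 alone, the 85 nt intron 2R from 1645331 to 1645415 had more, 3505.5 reads against 2704.5 in replicate 1. On 2R, the 4554 nt intron from 8147694 to 8152247 was crossed by about 3008 and 2396 reads, and coverage inside it was 0.128% ± 0.00209 of that in its flanks. The longest of all, 2L from 6101799 to 6121773, measured 19975 nt, near the upper limit of the search, and had far fewer junction reads, about 36.5 and 24.5 reads. These counts are the sizes of the coverage steps, averaged over both ends.

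**Figure D2:**
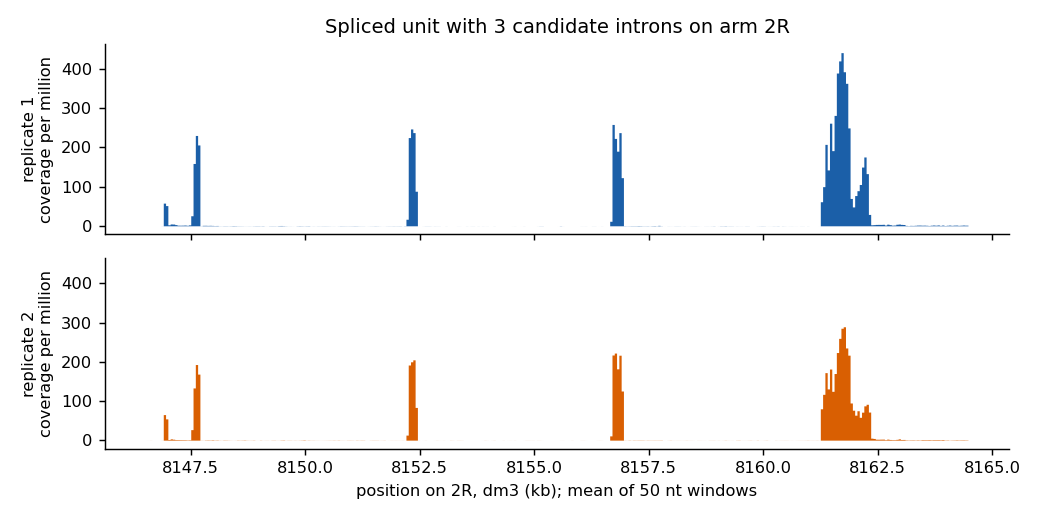
Coverage scaled to 1000000 reads (y axis, linear, means of 50 nt windows) along the unit of 2R from 8146896 to 8164049 of dm3 (x axis, kb) in replicate 1 (top) and replicate 2 (bottom). The 3 candidate introns, the longest of 4554 nt, are the wide gaps with almost no signal; the narrow gap near the left end is not a candidate intron and keeps a low signal.

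Coverage inside the candidate introns was compared with that of their flanks. A call needs a drop and a rise, each of at least 10 reads and 20% of the coverage at the base beside it. Median flanks were 26 reads in replicate 1 and 25.9 in replicate 2. Introns without such steps were not called, so the values below are not those of all introns. Coverage inside averaged 3.36% of the flanks in replicate 1 and 3.15% in replicate 2 (mean 3.25% ± 0.151), with medians of 1.09% and 1.11%, and 1899 candidate introns (22.1%) had no read inside in either library. The ratios of introns were related between the replicates, more closely by Pearson's r (0.855) than by the ranks of Spearman's rho (0.609). It differed with length. Mean coverage inside was 2.57% ± 0.0811 for the 5179 introns of 40 to under 100 nt, 4.15% ± 0.183 for 1850 of 100 to under 500 nt, 5.31% ± 0.428 for 959 of 500 nt to under 2 kb and 3.13% ± 0.215 for 618 of 2 kb or more. The medians were lower, 0.288% ± 0.0933, 1.61% ± 0.0221, 2.88% ± 0.282 and 1.64% ± 0.0295 in the same order of classes, so that by medians the longest class lay just above that of 100 to under 500 nt, and by means below it. The class of 500 nt to under 2 kb was highest and the shortest class lowest by both measures in both libraries. An exact paired test over 2 replicates cannot give a two-sided p below 0.5, so these differences were not tested further. The comparison of lengths has 2 limits. At flanks of about 26 reads, 1 read across a gap gives a ratio above 0.288%, so the median of the shortest class lies near the floor. A gap also ended at the next sharp rise, so long introns with sharp-edged signal inside were not called at full length.

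**Figure D3:**
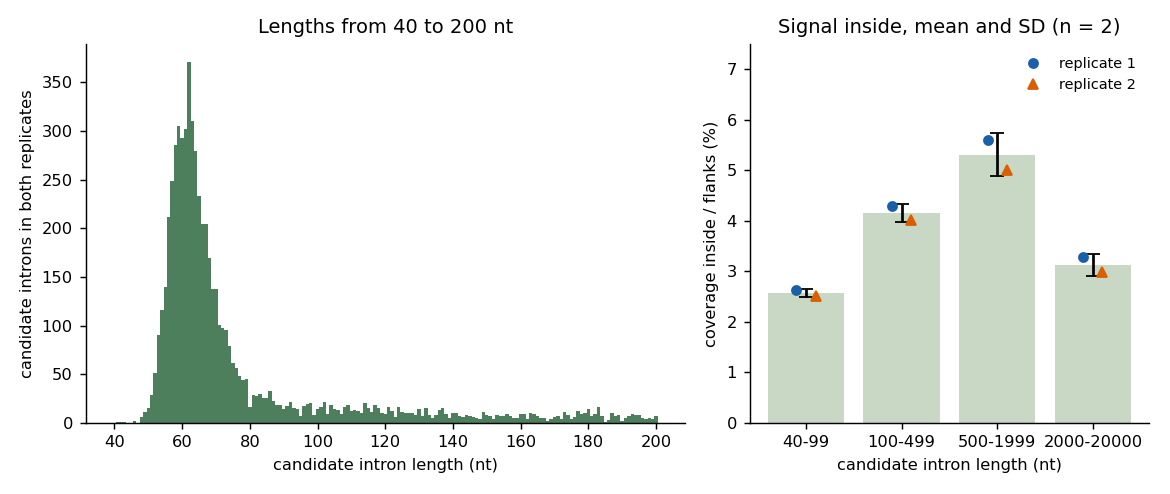
Left, number of candidate introns found in both replicates (y axis) at each length up to 200 nt (x axis), with the highest bar, 371, at 62 nt. Right, mean coverage inside as a percentage of the flanks (y axis) in 4 length classes (x axis); bars and whiskers are the mean and SD of the 2 replicates, points the replicates, with the highest mean, 5.31%, at 500 nt to under 2 kb.

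Some candidate introns kept substantial coverage. In 147 of the 8606 (1.71%) coverage inside was 20% or more of the flanks in both libraries; this share counts only gaps with a drop in coverage. The count was 226 in replicate 1 alone and 201 in replicate 2 alone, and 62 with steps of at least 20 reads. Among those with at least 100 reads in the flanks, the highest ratio was that of the 137 nt intron 2L from 10409375 to 10409511, 89.1% ± 5.86. Its steps averaged 27.5 reads in replicate 1 and 34 in replicate 2, small against mean flanks of 102.9 and 113.85 reads. Next came the 789 nt intron 3L from 224184 to 224972 at 53.0% ± 4.03 and the 102 nt intron X from 9445774 to 9445875 at 44.0% ± 2.12. Of those of 2 kb or more with such flanks, the highest was 3R from 3934101 to 3936798 at 10.5% in replicate 1 and 8.41% in replicate 2. Under 100 nt, the highest were 2R from 3353983 to 3354073 at 42.4% ± 4.16 and 3R from 7068015 to 7068055 at 40.3% ± 1.91. The latter measured 41 nt, near the lower limit of the search, and was the only 1 of that length. The neighbouring introns on 3L, from 16567853 to 16567952 and from 16568077 to 16568286, reached 24.6% ± 4.13 and 27.1% ± 1.53. Without strand, RNA from an overlapping gene cannot be told from unspliced RNA at these sites.

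Joining blocks through their introns gave 3963 spliced units on the arms, which held 44.7% of the signal. No gene names were given to them, since no annotation of this assembly was used. Of the units, 2026 (51.1%) had 1 intron and 346 had 5 or more. An intron that was not called in both libraries can split a gene into several units, so these are not intron counts of transcripts. With a block minimum of 6 reads there were 4491 units. The unit with the most introns, 2R from 579258 to 615155, had 18 over 35.9 kb and a mean exon coverage of 2.80 ± 0.440. The longest, 3R from 19431469 to 19485719, spanned 54.3 kb with 12 introns, one of 18417 nt, at 4.78 ± 0.0849. The highest coverage after the 3L locus at 2113290 was that of 3R from 19184518 to 19185810, at 186 ± 25.3, followed by 2L from 6966777 to 6967630 at 153 ± 6.43 and 2R from 15177603 to 15178470 at 116 ± 16.8. The 3L locus, from 2113290 to 2114127, had 6780 ± 863 over 167 nt in blocks separated by a gap of 671 nt with no read inside. That gap was not among the 5 with the most junction reads, so its mean over both libraries was at most 2367.5. The 1 kb bin from 2113001 held 264999 read equivalents in replicate 1 and 229380 in replicate 2. Most of the coverage of this locus therefore did not come from reads across the gap, and its level does not measure spliced RNA. Unit levels had a Pearson's r of 0.981 between replicates on the log2 scale, and 5 units differed by 2-fold or more. A unit needs coverage and the same introns in both libraries, so a locus that is low in either forms none. This agreement is therefore partly set by the rule.

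Mitochondrial signal was highest in 2 regions. The bins from 1001 to 2000 and from 2001 to 3000 had 150.1 ± 4.05 and 143 ± 60.7, and those from 12001 to 13000 and from 13001 to 14000 had 279 ± 63.5 and 187 ± 74.0. Of the bins between them, those from 3001 to 6000 had 32.0 ± 0.239, 14.6 ± 3.21 and 26.8 ± 20.8, and that from 11001 to 12000 had 37.7 ± 21.5. Between 6001 and 11000 the bins ranged from 0.664 ± 0.510 to 4.23 ± 4.14. In the bin from 12001 to 13000, the summit at 12829 was 50 nt wide at 50% of its height in both replicates. A summit at 13204, in the bin from 13001 to 14000, was 50.5 nt wide by the mean of both. Part of the signal in these 2 bins therefore lay in stacks about as wide as 1 read. Total mitochondrial signal was 2.19% of reads in replicate 1 and 1.44% in replicate 2, a log2 difference of −0.60, while the 6 arms together differed by −0.08.

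**Figure D4:**
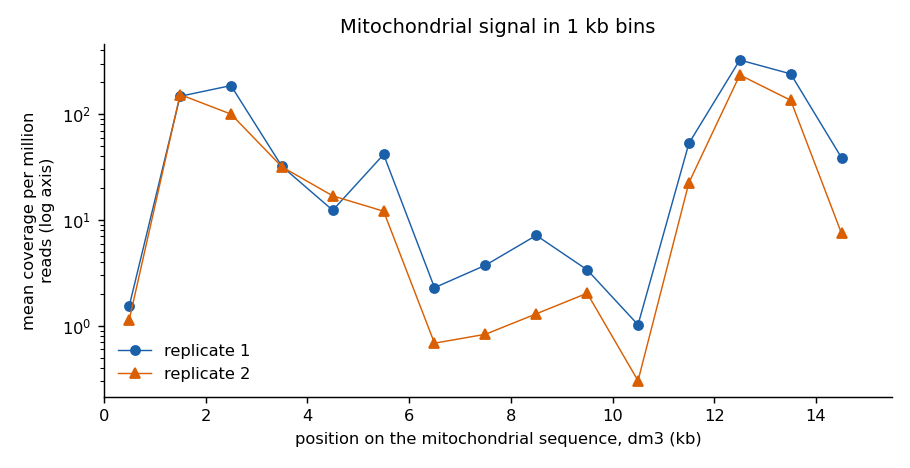
Mean coverage scaled to 1000000 reads (y axis, log) in 1 kb bins along the mitochondrial sequence of dm3 (x axis, kb) in replicate 1 (circles) and replicate 2 (triangles), for bins with a mean of 0.664 or more. The bin from 12001 to 13000 is the highest in both, and the bins from 5001 to 9000 and from 14001 to 15000 are lower in replicate 2.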

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

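The share of signal on the 6 euchromatic arms (77.3%) was 75.1% and 79.5% in the single replicates. It rose to 95.1% without mitochondrial and unplaced sequence and to 97.9% with each base capped at the 99th percentile, as tall stacks then count less. The correlation of bins (0.991) was 0.997 in 5 kb bins and 0.970 in the top 10% alone. The 49 differing bins became 10 of 2058 compared in 5 kb bins, 11 of 737 in the top 1% and 29 of 6971 on the arms alone, an alternative chosen after seeing the data. The signal in the top 1% of bins (51.2%) was 49.8% to 52.6% in single replicates, 47.1% in 5 kb bins and 40.8% without mitochondrial and unplaced sequence. The intron alternatives were chosen after the data were examined. Steps of at least 20 reads gave 4733 candidate introns in place of 8606 and 62 retained introns in place of 147. The mean inside was then 2.92% in place of 3.25%. Fewer gaps pass, and the cause of the lower mean was not tested. Steps of at least 50% of the coverage beside them gave a mean inside of 2.97%, a rule that leaves out gaps with smaller steps. Single replicates gave 11168 to 11808 candidate introns; over the 8606 shared ones they gave a mean inside of 3.15% to 3.36% and 201 to 226 retained introns. With 2 replicates, a mean over them cannot move by its SD when 1 is left out. Of the 20 other alternatives for these results 13 moved and 7 did not, and of 26 for the shares of single chromosomes 25 moved by more than the SD. Leaving out mitochondrial and unplaced sequence raises the share of every other sequence by arithmetic. The direction of those moves was thus fixed in advance and says nothing about stability. Depth limits the intron results to places with 10 or more reads across a junction. The planned results that need a gene annotation or the sequence of this assembly were not run.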

Other observations

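The tests on mitochondrial bins and on reading frame were chosen after their results had been seen in part; those on the shape of stacks and on the evenness of intron signal were written before. Among spliced units above the median level, 3R from 1020759 to 1027436 was higher in replicate 2 by a centred log2 ratio of 1.31 (coverage of 2.92 and 6.97), 3R from 4898603 to 4905559 by 1.09 and 3L from 2563789 to 2564603 by 1.04. In the other direction, X from 14733429 to 14735052 was at −0.82, 2L from 9935130 to 9935787 at −0.72 and 2L from 9177346 to 9191813 at −0.70. Each of these 6 units had 1 candidate intron, as did 51.1% of the 3963 units.

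Tall narrow stacks of coverage sat mostly outside the euchromatic arms. Of 21 summits with a mean coverage of 1000 or more, scaled to 1000000 reads, 18 were 45 to 55 nt wide at 50% of the height, the length of 1 read, and 17 of these 18 lay on unplaced, heterochromatic or mitochondrial sequence. Copies of one fragment with a single start would rise within 5 nt; the median rise from 10% to 90% of the height took 19.75 nt, which argues against that as the cause for the set, although 2 of the 18 rose within 5 nt. A candidate explanation is that reads were kept only where they overlap a base that sets one repeat copy apart, for which 25 nt or more was predicted; 19.75 nt lies below that and above the 10 nt that would speak against it, and 2 stacks reached 25 nt, so it stays open. Values on U and XHet may then depend on how the aligner treated repeats, and no biological explanation was tested.

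Mitochondrial signal was lower in replicate 2, in 11 of 14 bins after centring and by 2-fold or more in 6. One candidate explanation is the fixed total: unplaced and heterochromatic sequence took 18.3% of reads in replicate 1 and 23.5% in replicate 2, which lowers all else alike. An equal lowering would move the arms and the mitochondrial sequence alike. The 6 arms together differed by a log2 of −0.08 and total mitochondrial signal by −0.60, which argues against this as the whole cause. The median log2 ratio of the mitochondrial bins was −0.86, below the middle 95% (−0.26 to 0.09) of 10000 sets of arm bins at matched level. The first form of this test on bins, replaced because it set a total against single bins, had come out the other way: the total (−0.60) lay within the middle 95% of 129 arm bins (−0.68 to 0.85). That range is the spread of single arm bins and does not measure a lowering common to all of them. A single factor for all mitochondrial RNA, such as fewer mitochondria in one preparation, would move the bins together. Their centred log2 ratios ran from −2.29 to 0.54, with an SD of 0.91, above the highest of the 10000 sets (0.68). The sets drew each arm bin separately from anywhere on the large arms, while the mitochondrial bins are neighbours on 1 sequence. They may thus understate the spread to be expected of neighbours, for the median and for the SD. Degradation or uneven recovery of particular RNAs stays open, and no biological explanation was tested.

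Signal inside long candidate introns could come from unspliced RNA or from exons and transcripts that lie within them. In the 36 retained introns of 500 nt or more, a median of 0.778 of the inner bases had at least 50% of the intron's mean coverage. This does not decide between them, because a gap was taken to end at the next sharp rise. A sharp-edged exon of 150 nt that held all the inner signal would have ended the gap in 36 of the 36, so introns with such exons were left out before evenness was measured. Unspliced RNA, inner exons and a transcript of an overlapping gene cannot be told apart here.

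A further hypothesis was that retained introns keep the reading frame. Lengths that are a multiple of 3 made up 54 of the 147 retained candidate introns, 36.7% with an exact 95% interval of 28.9% to 45.1%, against 33.3% for no preference (exact binomial test, two-sided, p = 0.383). The introns under 100 nt gave 23 of 63. An excess was not detectable with this number of introns.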
